A study of Mus musculus with 4 samples.

How the data were processed

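The series holds single-cell RNA data from the visceral adipose tissue of C57BL/6 mice on 2 diets, a high-fat diet and normal chow (named LEAN in the labels). Per the labels, every mouse was 4 months old and had received tamoxifen, and each diet had 3 mice whose sorted cells carried hashtag antibodies 3, 4 and 5, 1 per mouse. The gate of that sort is not given in the sources, and the "+PL" code in the source name of the high-fat samples is not explained there. Each diet was loaded on 1 lane of a 10x Chromium version 3 chip with 36000 cells (12000 per mouse), so diet and lane cannot be told apart and no batch term could be fitted. Each diet gave a gene expression library and a hashtag library. One mouse (1 hashtag within 1 library) is 1 replicate, which leaves 3 mice per diet.

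The gene expression files hold counts of unique molecular identifiers (UMIs) per gene and barcode, deposited with every barcode of the chemistry and no cell calling. Per the labels' processing notes, they were made with bcl2fastq 2.20.0.422 and Cell Ranger 3.1.0 on the mm10/GRCm38 mouse genome. The deposited hashtag files hold raw counts per hashtag and barcode for 50000 (LEAN) and 100000 (high-fat) barcodes; the tool that made them, and whether it counted reads or UMIs, is not stated. Gene symbols were taken from the deposited files. The position of Cdkn1a came from a GRCm38 annotation matched by gene ID.

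Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Hashtag singlets were called with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99. Doublets of the same mouse, which hashtags cannot show, were called from the share of hashtag doublets among the 50 nearest neighbours of each cell, up to the number that the hashtag doublet rate predicts, and left out. Kept singlets and cells without a hashtag of both libraries were clustered together with no batch integration. The steps were normalisation to 10000 UMIs per cell, 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2, resolution 1), which gave 29 clusters. A cluster took an "X-like" name from 145 fixed marker genes. A marker counted as raised at 4 times its median over clusters (with the median set to at least 5 CPM, UMI counts scaled to the depth of a sum) and in at least 10% of the cluster's cells. The type with the largest share of raised markers gave the name, if that share was at least 40% and at least 3 markers were detected. Where another type had more markers among the cluster's top 10 genes, that type gave the name at a share of 70%, and otherwise the cluster stayed unnamed. 27 clusters fell into 13 classes, and clusters 15 and 20 stayed unnamed. Classes with at least 20 cells in each of the 6 mice were tested, which left 8.

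UMI counts were summed per mouse and class and tested with edgeR 4.0.16 (TMM normalisation, filterByExpr, quasi-likelihood test) on the 6 sums of a class, with diet as the only term. P-values were adjusted by the Benjamini-Hochberg method within each class, with a threshold of 0.05. Every adjusted p for a gene comes from this test unless another tool is named, and SE is the standard error of the log2 fold change. The difference of the diet effect between classes was tested with a class by diet term over mouse blocks, for the 3 pairs of progenitor-like, macrophage-like and endothelial-like cells. In these classes cells with and without a Cdkn1a UMI were also compared. Cells were first thinned to 1000 UMIs, and the unthinned counts of both kinds of cell were summed per mouse with the mouse as a block. A mouse entered with at least 10 cells of each kind, and Cdkn1a was left out of the genes tested. A diet by Cdkn1a term tested whether that contrast differed between diets. Shares of cells were compared with exact permutation tests over mice, two-sided, which with 3 against 3 cannot go below 0.1. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and classes. A list needed at least 5 measured members in a class.

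20 gene lists with 309 genes were fixed: cell cycle inhibitors, senescence-associated secretory factors, p53 target, NF-kB target, lipid-associated macrophage, resident macrophage, extracellular matrix, adipogenic, Dpp4-expressing progenitor, interferon-stimulated, MHC class II, hypoxia and glycolysis, oxidative phosphorylation, dissociation stress, proliferation, capillary lipid-handling, endothelial activation, regulatory T cell, T cell activation and exhaustion, and insulin signalling genes. Lists share members, so their tests are not independent. Genes named in the text followed a fixed rule. In progenitor-like, macrophage-like and endothelial-like cells these were the 10 genes with the largest and the 10 with the smallest log2 fold change among those past the threshold, with an average log2 CPM of at least 5 and no overlap between the mice of the diets; in other classes they were 3 and 3. Predicted genes, mitochondrial and ribosomal genes and antigen receptor segments were left out. Cdkn1a was named in every class. Of each list, the 4 members with the smallest p in a class could be named. For class by diet and Cdkn1a comparisons the rule took 5 and 5, without the overlap condition. The filters, markers, lists, rule, tests and most alternative settings were set before the data were examined. 1 gene that the rule took in progenitor-like cells is not reported here.

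After the data were seen, a second fit of each class was added because many cells held genes of another class. A cell was called mixed when genes of another class reached 20% of their median level in that class, with at least 3 such UMIs. The genes were Dcn, Col1a1 and Col3a1 of progenitor-like cells (not applied to mesothelial-like and mural-like cells), C1qa, C1qb and C1qc of macrophage-like cells (not applied to monocyte-like and dendritic-like cells), and Cldn5, Cdh5, Egfl7, Flt1 and Kdr of endothelial-like cells. Mixed cells were left out, and the RNA profile of droplets with 100 to 500 UMIs (free RNA) was subtracted from the sums, at the median UMI count of such droplets for each cell, 122 in the LEAN and 393 in the high-fat library. This is called the corrected fit. Its named genes follow the same rule. The planned subtraction used droplets under 100 UMIs at a share of 49.5% (LEAN) and 20.3% (high-fat), the larger of 2 estimates from genes that a class should lack (C1q genes in lymphocytes, Dcn and Col3a1 in immune cells), and is reported only as an alternative. The share of cells that free RNA alone would give a Cdkn1a UMI, from the same droplets at 1000 UMIs per cell, was also added then. The T-like, B-like and neutrophil-like classes, with at least 10 cells in each mouse, were also tested only after the data were seen.

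The libraries held 263083213 (LEAN) and 152435459 (high-fat) UMIs over 6794880 barcodes and 31053 genes. The analysed mice had between 1168 and 3598 cells. Counting limits matter most for classes near 20 cells per mouse: the smallest sums had 25 mural-like cells and 30 monocyte-like cells. Where a diet's mice were all at 0 for a gene, the fold was given as a lower bound from a floor of 3 counts over the diet. Intervals for shares are exact (Clopper-Pearson, 95%) and cover counting error only.

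The scripts were tested on simulated data with 200 changed genes per comparison. The diet test recovered between 21% (mural-like) and 75% (progenitor-like) of 2-fold changes and between 90% (macrophage-like) and 100% (dendritic-like, endothelial-like) of 4-fold changes. Between 2.54% (mural-like) and 6.99% (macrophage-like) of its calls were false. The class by diet test recovered 38% of 2-fold differences in both pairs with progenitor-like cells and 16% for macrophage-like against endothelial-like cells. The Cdkn1a UMI test recovered 44% (progenitor-like), 97% (macrophage-like) and 87% (endothelial-like) of 2-fold differences, and its diet term 0%, 25% and 30%.

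Alternatives were relative log expression normalisation, no filter on low counts, the DESeq2 1.42.0 Wald test, looser cell filters (500 UMIs, 300 genes, 20% mitochondrial), stricter hashtag calls (the highest hashtag 3 times the next), same-mouse doublets kept, the planned subtraction, the hashtag number as a block, leaving out each mouse, thinning to 2000 UMIs or not at all, at least 2 Cdkn1a UMIs, and thinned sums. Added after the data were seen were the corrected fit, each of its parts alone, leaving out cluster 21 (low UMI counts), and fits within 1 cluster. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Left out were barcodes under the filters, hashtag doublets, cells without a hashtag (except where stated), and plasma-like and mast/basophil-like cells, which were too few to test.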

Results

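Cells from visceral adipose tissue were profiled from 3 mice fed a high-fat diet and 3 fed normal chow (LEAN). The source name of the high-fat samples also carries a "+PL" code, which the sources do not explain and which goes with diet. The series sets out to study senescence in insulin resistance, so Cdkn1a, which encodes the cell cycle inhibitor p21 and is used as a senescence marker, was followed in every class of cells. 18305 LEAN and 9160 high-fat barcodes passed the filters, with medians of 11003 and 10100.5 UMIs and 3403 and 3034 genes, and these barcodes held 89.3% and 76.1% of the UMIs of their libraries. Of these, 17828 and 9132 had hashtag counts. Hashtags assigned 9753 and 5938 cells to 1 mouse, while 37.2% (LEAN) and 31.2% (high-fat) of those with counts carried no hashtag that could be called. After the removal of doublets 9123 and 5696 cells remained: 2377, 3598 and 3148 in LEAN mice 3, 4 and 5 and 1168, 1265 and 3263 in high-fat mice 3, 4 and 5. High-fat mouse 4 (12867186 UMIs) and high-fat mouse 3 (14723280 UMIs) were the shallowest, and LEAN mouse 4 (49713345 UMIs) the deepest. Droplets too small to hold a cell, with 100 to 500 UMIs, had a median of 122 UMIs in the LEAN and 393 in the high-fat library. Estimates of the share of free RNA in cells differed in direction: C1q genes in lymphocytes gave 7.97% (LEAN) and 17.9% (high-fat), and Dcn and Col3a1 in immune cells 49.5% and 20.3%.

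Which cell classes made up the tissue on each diet was asked first. Macrophage-like cells, the scavenging and lipid-clearing cells of the tissue, made up 44.2 ± 19.2% of the cells of high-fat mice and 5.63 ± 3.83% of those of LEAN mice (mean ± SD, n = 3 mice per diet). Endothelial-like cells, which line vessels, made up 12.4 ± 1.15% against 5.73 ± 0.317%. Mesothelial-like cells, the outer covering of visceral fat, made up 7.31 ± 4.53% against 36.7 ± 6.93%, neutrophil-like cells 1.18 ± 0.378% against 8.42 ± 4.90%, and T-like cells 2.42 ± 1.41% against 6.01 ± 1.06%. In each of these 5 classes the mice of the 2 diets did not overlap (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 mice allow). Progenitor-like cells, the stromal cells that can become adipocytes, made up 5.54 ± 4.14% on high-fat diet and 11.1 ± 2.06% on chow (p = 0.2 in the same exact test), dendritic-like cells 5.99 ± 2.82% and 8.46 ± 0.758% (p = 0.2), and monocyte-like cells 7.68 ± 8.55% and 2.19 ± 1.04% (p = 0.4), with 17.5% in high-fat mouse 4 alone. Unnamed cluster 15 (Wnt4, Cldn3, Krt8) held 2.34 ± 3.39% and 3.27 ± 0.919%, and unnamed cluster 20 (Arg1, Spp1, Cd5l) 3.25 ± 3.95% and 2.03 ± 2.17%. No share passed adjustment over the classes (smallest adjusted p = 0.217 in the exact permutation test), and the sort gate, which the sources do not give, and the hashtags both act on these shares.

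**Figure D1:**
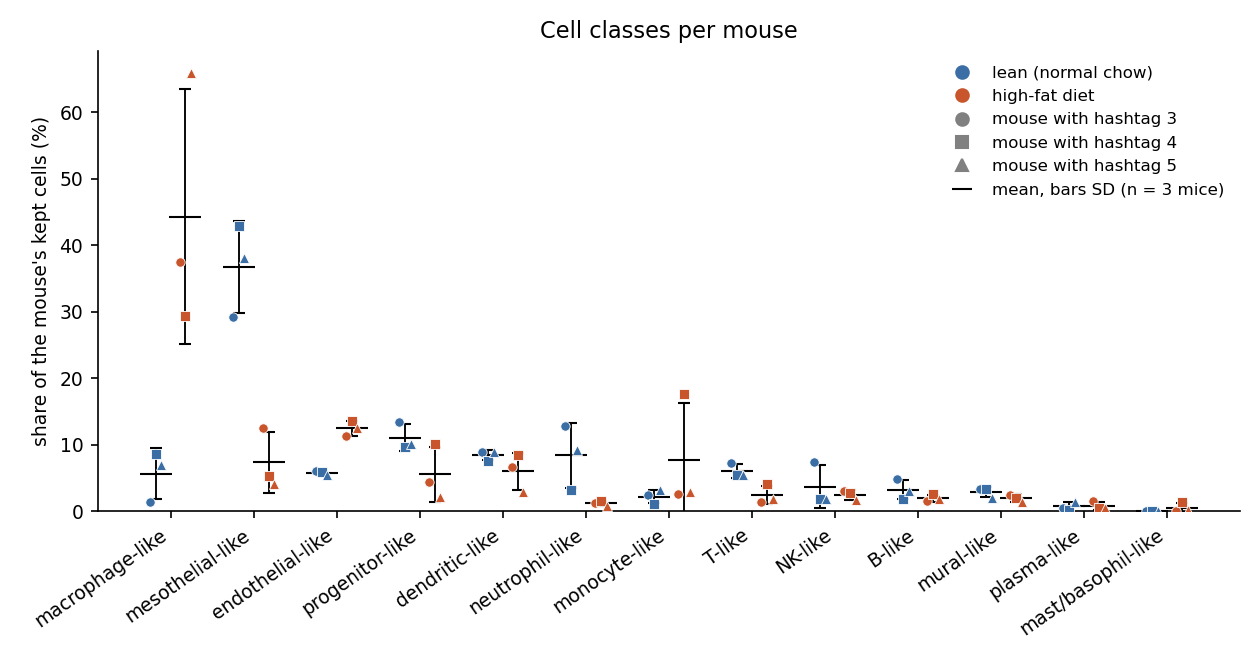
Share of each mouse's kept cells (%, vertical axis) in each named class on chow (LEAN) and on high-fat diet (HFD), where points are mice, black bars are means with SD, n = 3 mice per diet. Macrophage-like cells averaged 5.63% on chow and 44.2% on high-fat diet, and mesothelial-like cells 36.7% and 7.31%.

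The hashtags reached the classes unevenly. Only 14.3% of LEAN and 9.12% of high-fat progenitor-like cells carried a hashtag, against 39.9% and 61.1% of mural-like cells. When all cells of a library were counted, with a hashtag or without (15740 LEAN, 8543 high-fat), progenitor-like cells were the largest class on chow at 43.7% (95% interval 42.9 to 44.5%) and made up 31.7% (30.7 to 32.7%) on high-fat diet. Macrophage-like cells then made up 3.56% (3.27 to 3.86%) and 35.8% (34.7 to 36.8%), mesothelial-like cells 23.5% (22.9 to 24.2%) and 5.07% (4.61 to 5.56%), and endothelial-like cells 3.53% (3.24 to 3.83%) and 9.47% (8.86 to 10.1%). These are 1 library per diet, and the intervals cover counting error only.

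Within the classes, clusters divided by diet. LEAN macrophage-like cells came mostly from cluster 7 (470 cells with a hashtag), which is high in the resident macrophage genes Lyve1, Cd163 and Retnla. High-fat macrophage-like cells came from clusters 6, 8 and 7 (1132, 1016 and 628 cells). Cluster 6 (6 cells on chow) is high in the lipid-laden macrophage genes Mmp12, Gpnmb and Trem2. Of its cells 912 came from high-fat mouse 5, while in high-fat mouse 3 cluster 7 led (219 cells, 59 in cluster 6). Progenitor-like cells came mostly from clusters 0, 1 and 5 on chow (431, 300 and 142 cells) and from cluster 3 on high-fat diet (209 cells, against 86 on chow). Mesothelial-like cells came from clusters 2, 9 and 14 on chow (2269, 749 and 417 cells) and from clusters 9 and 2 on high-fat diet (246 and 98). Mural-like cells came from clusters 16, 22 and 23, with 112, 85 and 63 cells on chow and 16, 11 and 72 on high-fat diet. Dendritic-like cells came on both diets from cluster 13 (359 and 123 cells), with the cross-presentation genes Xcr1 and Clec9a, cluster 18 (318 and 98 cells), with the migration genes Ccr7 and Ccl22, and cluster 25 (88 and 58 cells), with the plasmacytoid gene Siglech. A class value below can therefore change because its clusters changed in proportion.

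Whether Cdkn1a changed with diet was then tested in each class. The gene lies on GRCm38 chromosome 17 from 29090976 to 29100727 on the plus strand and is protein coding. Cdkn1a rose 4.14-fold on high-fat diet in dendritic-like cells (log2 fold change 2.05, SE 0.22, adjusted p = 3.32e-04), from 52.9 ± 7.99 to 201 ± 54.8 CPM (mean ± SD, n = 3 mice per diet). In mural-like cells, the contractile cells around vessels, it rose 3.08-fold (1.62, SE 0.23, adjusted p = 4.00e-03), from 123 ± 19.3 to 388 ± 97.3 CPM. Monocyte-like cells showed a 2.06-fold rise (1.04, SE 0.19, adjusted p = 9.73e-03), from 264 ± 42.9 to 534 ± 32.9 CPM, and progenitor-like cells a 1.61-fold rise (0.69, SE 0.21, adjusted p = 0.0349), from 49.9 ± 9.2 to 72.8 ± 23.2 CPM. The log2 fold change was 0.68 (SE 0.27, adjusted p = 0.120) in mesothelial-like, 0.34 (SE 0.16, adjusted p = 0.120) in macrophage-like and 0.33 (SE 0.28, adjusted p = 0.496) in endothelial-like cells. Endothelial-like cells were among the highest in Cdkn1a on both diets, with 429 ± 129 and 529 ± 200 CPM. In NK-like cells (26.8 ± 12.4 and 60.3 ± 44.5 CPM) the gene was below the count filter.

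The dendritic and monocyte changes stayed past the threshold in the corrected fit (log2 fold change 2.14, SE 0.242, adjusted p = 3.62e-04, and 0.95, adjusted p = 0.0470), but the planned subtraction ended the monocyte call (0.65, adjusted p = 0.188). In dendritic-like cells Cdkn1a also rose within cluster 13 (2.53, SE 0.42, adjusted p = 4.59e-03) and cluster 18 (2.17, SE 0.232, adjusted p = 2.29e-04). The mural change did not pass there (1.56, adjusted p = 0.309). Of high-fat mural-like cells 54.5%, and of LEAN ones 8.08%, held genes of endothelial cells, which are high in Cdkn1a. The progenitor change did not pass in the corrected fit (0.66, adjusted p = 0.0587) or within cluster 3 (0.09, SE 0.38, adjusted p = 0.926). It was also lost when LEAN mouse 4 (0.52), LEAN mouse 5 (0.68), high-fat mouse 4 (0.41) or high-fat mouse 5 (0.68) was left out. In macrophage-like cells the value passed when high-fat mouse 3 was left out (0.49) and within cluster 7 (0.69, SE 0.15, adjusted p = 6.94e-03). It was 0.05 in the corrected fit (adjusted p = 0.893) and −0.33 with the planned subtraction (adjusted p = 0.313). The endothelial value was −0.07 (adjusted p = 0.931) and −0.21 (adjusted p = 0.805) in these fits.

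**Figure D2:**
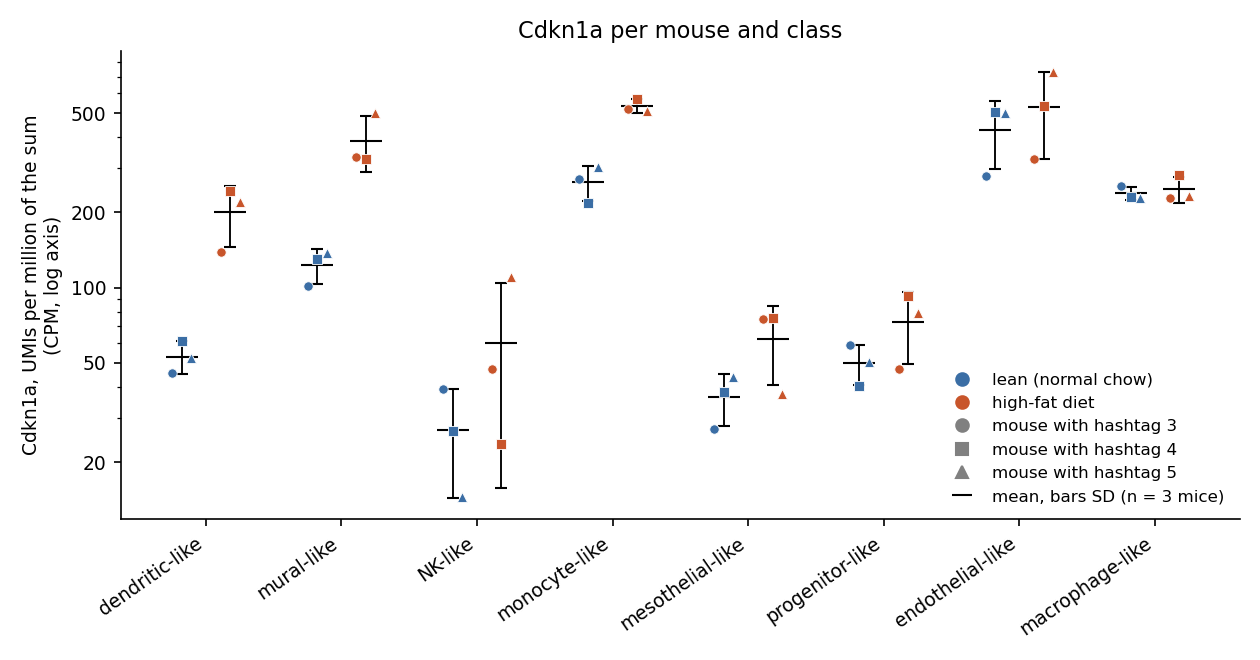
Cdkn1a in CPM (UMI counts scaled to the depth of each sum, logarithmic vertical axis) in the 8 tested classes on chow (LEAN) and on high-fat diet (HFD), where points are the sums of each mouse, bars are means with SD, n = 3 mice per diet. Dendritic-like cells averaged 52.9 CPM on chow and 201 CPM on high-fat diet, and endothelial-like cells 429 and 529 CPM.

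The share of cells with at least 1 Cdkn1a UMI was compared after each cell was thinned to 1000 UMIs. It was 40.0 ± 2.91% of monocyte-like cells on high-fat diet against 18.1 ± 4.83% on chow, 23.4 ± 5.85% against 10.0 ± 3.55% of mural-like cells and 16.8 ± 3.79% against 3.92 ± 1.33% of dendritic-like cells. Macrophage-like cells had 20.3 ± 1.51% against 17.0 ± 0.81%, neutrophil-like cells 17.3% against 9.40%, T-like cells 9.83 ± 3.1% against 2.44 ± 0.921% and NK-like cells 5.70% against 1.34% (exact permutation test, two-sided, p = 0.1 in each of these 7 classes, n = 3 mice per diet). B-like cells had 3.58 ± 2.12% against 1.28 ± 1.51% (exact permutation test, p = 0.2). Free RNA held Cdkn1a at 170 CPM on high-fat diet and 56.3 CPM on chow, so background shares differ by diet too. At the UMIs of free RNA per droplet, it alone would give 2.70% against 0.196% in B-like, 2.72% against 0.305% in NK-like, 2.77% against 0.279% in T-like and 4.00% against 0.474% in neutrophil-like cells. In monocyte-like, dendritic-like, mural-like and macrophage-like cells it would give 2.02%, 1.46%, 1.11% and 0.933% on high-fat diet. Endothelial-like cells had 36.0 ± 9.78% against 42 ± 3.25%, progenitor-like cells 6.42 ± 3.92% against 4.41 ± 1.70% and mesothelial-like cells 6.63 ± 4.04% against 2.99 ± 0.725% (exact permutation test, p = 0.5, 0.6 and 0.3). At 2 UMIs the macrophage and progenitor differences turned (−0.255 and −0.433 points), as did the progenitor one without high-fat mouse 4 (−0.243) and the endothelial one without thinning (7.35). No share passed adjustment over the classes (smallest adjusted p = 0.157 in the exact permutation test).

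Progenitor-like cells on high-fat diet had higher Mmp3, a matrix metalloproteinase (log2 fold change 3.28, SE 0.39, adjusted p = 2.29e-04, 15.7 to 133 CPM), and Col8a1, a short-chain collagen (3.17, SE 0.26, adjusted p = 3.19e-05, 31.2 to 277 CPM). Lgals3, which encodes galectin-3 (2.65, SE 0.27), the chemokine Ccl8 (2.63, SE 0.30) and the macrophage gene Lyz2 (2.36, SE 0.24) rose. The growth factor Mdk (2.30, SE 0.14, adjusted p = 4.71e-06), the acid phosphatase Acp5 (2.28, SE 0.20), Vtn, which encodes vitronectin (2.15, SE 0.40), and the lysosomal protease Lgmn (2.14, SE 0.19) rose too. The B cell chemoattractant Cxcl13 fell (−4.36, SE 0.91, adjusted p = 6.08e-03, 568 to 35 CPM). The vasoconstrictor peptide gene Edn1 (−3.91, SE 0.36), the neutrophil gene S100a9 (−3.69, SE 0.97) and the protease gene Adamts16 (−3.42, SE 0.34) fell too. The heat shock gene Hspa1b fell from 556 to 53.1 CPM (−3.37, SE 0.13, adjusted p = 1.64e-07) and Sult1e1 from 869 to 119 CPM (−2.92, SE 0.29). Also lower were Smpd3 (−3.34, SE 0.32), Inmt (−3.15, SE 0.23), the mesothelial gene Clu (−2.97, SE 0.21) and Gpc3 (−2.93, SE 0.19). All these genes kept their direction and passed in the corrected fit, where Lyz2 was at 1.77 (SE 0.37) and Lgals3 at 2.18 (SE 0.38). That fit removes no mesothelial-mixed or neutrophil-mixed cells, so mixing stays open for Clu and S100a9. Of 11014 genes tested, 1237 rose and 1092 fell, and DESeq2 called 1669. The 2329 calls became 1552, 1399 and 1478 without LEAN mouse 4, LEAN mouse 5 and high-fat mouse 4. Within cluster 3, which held most high-fat progenitor-like cells and has Mmp3, Mdk and Col8a1 among its top markers, 649 of 6826 genes passed. Cxcl13, Inmt and Sult1e1 are top markers of cluster 0.

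In these progenitor-like cells 17 of 19 measured lipid-associated macrophage genes, which serve lipid uptake and lysosomal digestion, rose and none fell (18 and 0 when adjusted over the list alone). Examples were Mmp12 (7.84, SE 0.37), Gpnmb (1.86, SE 0.15) and the fatty acid transporter Cd36 (2.07, SE 0.17). The camera test gave an adjusted p = 6.88e-27 (adjusted p = 0.0426 with an estimated correlation). With the subtraction of free RNA planned in advance the direction of this test turned (median 1.49 to 0.17), and so did Gpnmb (−9.28). Cells with macrophage genes (C1q) were 0.305% of LEAN and 0.405% of high-fat progenitor-like cells. 14 of 16 dissociation stress genes fell (14 adjusted over the list alone), among them Zfp36 (−1.24, SE 0.10), Egr1 (−0.96, SE 0.10) and Hspa1a (−2.54, SE 0.17, but 1.93 with the planned subtraction). Camera gave these an adjusted p = 1.99e-22 (adjusted p = 0.0641 with an estimated correlation). 9 of 11 Dpp4-expressing progenitor genes, which mark early stromal progenitors, fell (10 adjusted over the list alone), with Dpp4 at −1.80 (SE 0.25), Cd55 at −1.07 (SE 0.15) and Sema3c at −1.75 (SE 0.26). That list had an adjusted p = 1.01e-09 (adjusted p = 0.250 with an estimated correlation). Of 25 extracellular matrix genes 12 rose and 1 fell (14 and 1 adjusted over the list alone), led by Mmp14 (1.47, SE 0.10), Col4a2 (1.28, SE 0.14), Col4a1 (1.07, SE 0.12) and Bgn (0.70, SE 0.08). Here the adjusted p was 9.15e-08 (adjusted p = 0.250 with an estimated correlation).

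Of 31 senescence-associated secretory factors 13 rose and 1 fell in progenitor-like cells (14 and 3 adjusted over the list alone). Gdf15 (3.35, SE 0.32) and Ccl8 rose, but are top markers of macrophage-like clusters, so macrophage RNA stays open for them. The list passed camera (adjusted p = 3.35e-09, or 0.174 with an estimated correlation). Of 9 cell cycle inhibitors 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.402). Cdkn2c (0.88, SE 0.15) and Cdkn2d (0.73, SE 0.20) rose with Cdkn1a, while Cdkn2b (−2.04, SE 0.43) and Cdkn1c (−0.76, SE 0.20) fell. Of 10 insulin signalling genes 7 fell and 1 rose, the same when adjusted over the list alone (adjusted p = 9.50e-03, and adjusted p = 0.250 with an estimated correlation). The insulin receptor substrate Irs1 (−1.26, SE 0.22), Pdk4 (−1.33, SE 0.24) and the adaptor Grb10 (−0.55, SE 0.12) fell. Ptpn1, an insulin receptor phosphatase, rose (0.89, SE 0.12). 14 of 34 oxidative phosphorylation genes rose and none fell (17 and 0 adjusted over the list alone, adjusted p = 1.22e-05, and adjusted p = 0.428 with an estimated correlation). 7 of 15 adipogenic genes rose and 2 fell, the same when adjusted over the list alone, with Lpl (1.14, SE 0.14) and Apoe (1.56, SE 0.19) up and Agt (−1.36, SE 0.18) down. Their adjusted p was 5.16e-03 (adjusted p = 0.262 with an estimated correlation), and the direction turned with the planned subtraction (median 0.15). Of 20 p53 target genes 4 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.149).

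Macrophage-like cells had the most genes changed. The elastase Mmp12 went from 20.4 to 1495 CPM (log2 fold change 6.12, SE 0.73, adjusted p = 1.01e-04), Gpnmb from 68.8 to 2024 CPM (5.20, SE 0.42, adjusted p = 7.61e-06) and the fatty acid binding protein gene Fabp5 from 57.0 to 1533 CPM (5.08, SE 0.33, adjusted p = 2.38e-06). Zranb3 (5.45, SE 0.64), Cdk18 (5.35, SE 0.50), Atp6v0d2 (5.34, SE 0.36), F7 (5.34, SE 0.42), Rnf128 (5.25, SE 0.69), Adam8 (5.14, SE 0.44) and Cd5l (4.90, SE 1.29) rose as well. Genes usually expressed by stromal cells fell: Sult1e1 (−6.14, SE 0.38), Inmt (−5.49, SE 0.49), Penk (−4.69, SE 0.32), Ogn (−4.20, SE 0.25), Sema3c (−4.13, SE 0.27) and Dpep1 (−4.12, SE 0.32). So did Hspa1b (−4.56, SE 0.59, 1388 to 51.3 CPM), Ackr3 (−4.19, SE 0.20), Apod (−3.99, SE 0.17) and Hp (−3.93, SE 0.45). 16.4% of LEAN and 4.77% of high-fat macrophage-like cells also held progenitor genes.

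In the corrected fit of macrophage-like cells Mmp12 (5.32, SE 0.69), Gpnmb (5.40, SE 0.64), Fabp5 (5.02, SE 0.35) and Atp6v0d2 (4.69, SE 0.35) passed. Sult1e1 was at −3.09 and Ogn at −1.93, Ackr3 did not pass (−1.37, adjusted p = 0.131), and Penk and Sema3c were no longer measured. There the rule also named Ctsk, a collagen-degrading cathepsin, as higher (6.59, SE 0.70). It named the resident macrophage genes Cd163 (−2.67, SE 0.40, adjusted p = 1.10e-03) and Retnla (−2.61, SE 0.58, adjusted p = 7.78e-03), Mgl2 (−3.27, SE 0.50), Vcam1 (−3.09, SE 0.27) and Fkbp5 (−3.75, SE 0.27) as lower. Of 10920 genes tested with all cells 2065 rose and 2219 fell (DESeq2 called 3621). The corrected fit called 2627, and without LEAN mouse 5 the 4284 calls became 2705. Within cluster 7, 1968 of 9202 genes passed.

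All 20 lipid-associated macrophage genes rose in macrophage-like cells (20 adjusted over the list alone), among them Lgals3 (4.78, SE 0.34) and the lipid receptor Trem2 (3.86, SE 0.27). Camera gave an adjusted p = 2.39e-25 (adjusted p = 0.174 with an estimated correlation). 19 of 20 rose in the corrected fit, and within cluster 7 14 of 19 rose and 1 fell. Of 14 resident macrophage genes 3 fell and none rose (2 adjusted over the list alone, adjusted p = 0.290), and 6 fell in the corrected fit. Within cluster 7, however, 11 resident genes rose and 1 fell. 9 of 16 hypoxia and glycolysis genes rose and 1 fell (10 and 1 adjusted over the list alone). The glycolytic enzyme genes Ldha (1.80, SE 0.21), Gapdh (1.74, SE 0.23) and Aldoa (1.91, SE 0.28) rose and Adm, a vasodilator gene, fell (−3.79, SE 0.38). The list had an adjusted p = 1.55e-03 (adjusted p = 0.266 with an estimated correlation). 28 of 34 oxidative phosphorylation genes rose (29 adjusted over the list alone), and 16 did in the corrected fit (adjusted p = 1.22e-06 with all cells, and adjusted p = 0.456 with an estimated correlation). 15 of 17 proliferation genes rose (17 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation), and 7 did in the corrected fit.

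14 of 16 dissociation stress genes fell in macrophage-like cells (15 adjusted over the list alone), with Jund (−1.50, SE 0.17) and Hspa1a (−3.48, SE 0.50) (adjusted p = 4.42e-05, and adjusted p = 0.355 with an estimated correlation). 23 of 24 extracellular matrix genes, which stromal cells make, fell (23 adjusted over the list alone, adjusted p = 9.77e-26, and adjusted p = 0.174 with an estimated correlation), but 7 of 22 did in the corrected fit. The senescence-associated secretory factors split into 9 that rose and 10 that fell of 33 (9 and 14 adjusted over the list alone, adjusted p = 0.376). Of 7 cell cycle inhibitors 1 fell, Cdkn1b (−0.89, SE 0.20).

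**Figure D3:**
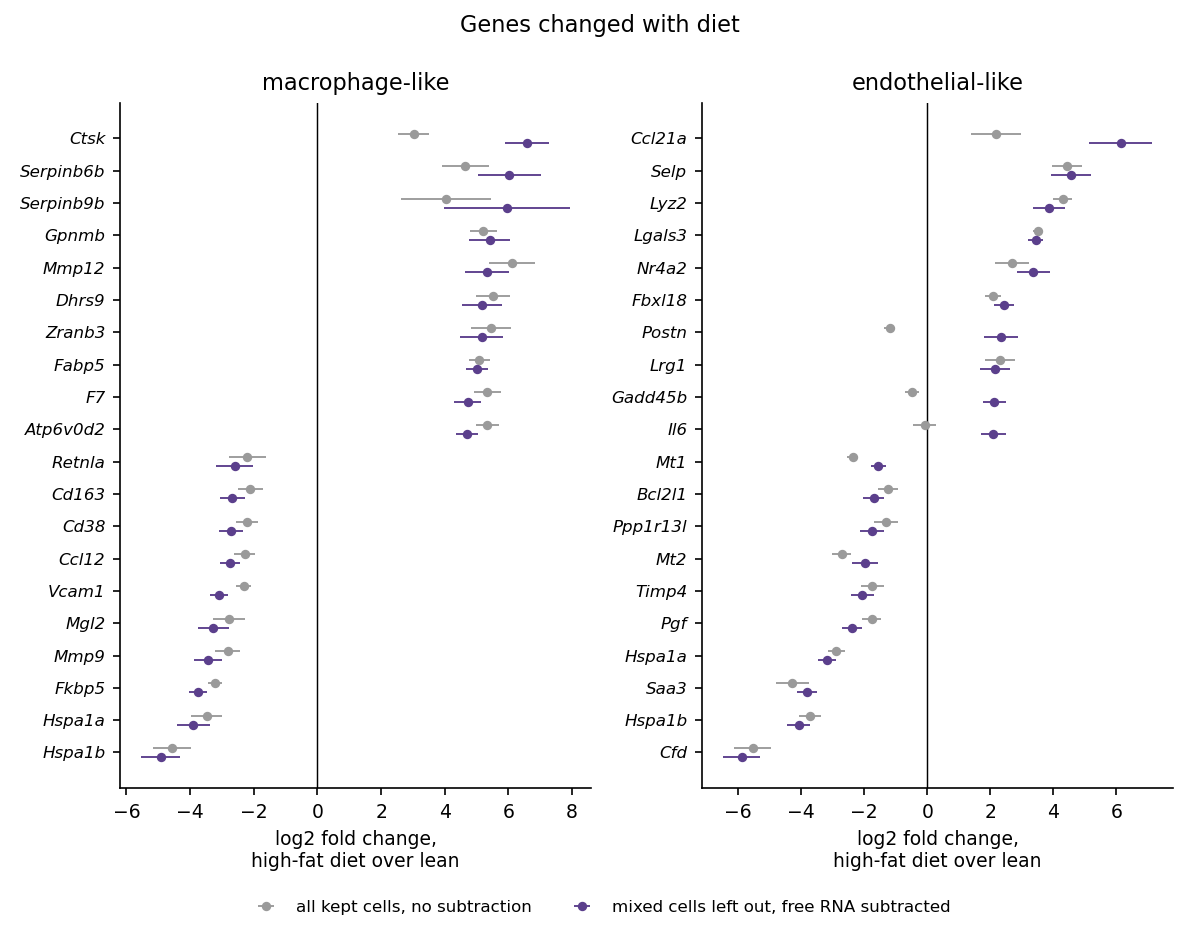
Log2 fold change on high-fat diet against chow (horizontal axis, ± SE, n = 3 mice per diet) of the genes that the naming rule took in the corrected fit, in macrophage-like and endothelial-like cells; grey points use all kept cells, purple points leave out mixed cells and subtract free RNA. Macrophage Gpnmb was at 5.20 and 5.40, while endothelial Postn was at −1.18 and 2.34 in the 2 fits.

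In endothelial-like cells Selp, the P-selectin gene, rose from 3.06 to 72.8 CPM on high-fat diet (log2 fold change 4.43, SE 0.48, adjusted p = 8.05e-05). Lgals3 rose from 31.8 to 361 CPM (3.52, SE 0.16, adjusted p = 3.92e-07). Genes usually expressed by macrophages rose: Lyz2 (4.30, SE 0.31), C1qc (3.71, SE 0.34), Cd68 (3.69, SE 0.33), C1qb (3.47, SE 0.30), Ccl4 (3.38, SE 0.28), Ctss (3.34, SE 0.28) and Ccl6 (3.28, SE 0.27), and Mmp12, which had no count on chow, was at least 58.7-fold higher. Cfd, an adipokine (−5.53, SE 0.59, 235 to 6.88 CPM), Lcn2 (−4.52, SE 0.71), Saa3 (−4.27, SE 0.51), Hp (−3.39, SE 0.44) and Hspa1b (−3.72, SE 0.36) fell. So did the stromal genes Inmt (−4.45, SE 0.31), Sema3c (−4.14, SE 0.26), Sfrp2 (−4.02, SE 0.43), Sult1e1 (−3.81, SE 0.46) and Penk (−3.74, SE 0.26). Progenitor genes were found in 12.7% of LEAN and 6.2% of high-fat endothelial-like cells, and macrophage genes in 0.192% and 2.11%. In the corrected fit Selp (4.56, SE 0.64), Lgals3 (3.44, SE 0.24), Lyz2 (3.86, SE 0.49), Cfd (−5.87, SE 0.59), Saa3 (−3.81, SE 0.33) and Hspa1b (−4.08, SE 0.37) passed. Ccl4 (1.92, adjusted p = 0.0635), Ctss (2.16, adjusted p = 0.0776) and Hp (−2.19, adjusted p = 0.111) did not, and C1qb, C1qc, Lcn2 and the 5 stromal genes were not measured. For Saa3, a top mesothelial marker, mixing stays open, as that fit kept mesothelial-mixed cells. It also named Ccl21a (6.13, SE 0.99), Postn (2.34, SE 0.55), Gadd45b (2.13, SE 0.36) and Il6 (2.10, SE 0.40) as higher, with values of 2.18, −1.18, −0.48 and −0.09 when all kept cells were used. It named the angiogenic factor Pgf (−2.37, SE 0.31) and the metal-binding genes Mt2 (−1.97, SE 0.41) and Mt1 (−1.55, SE 0.23) as lower.

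Of 8911 genes tested in endothelial-like cells 473 rose and 720 fell, and 202 passed in the corrected fit. The 1193 calls became 721 without LEAN mouse 4 and 717 without high-fat mouse 5. Endothelial activation genes split into 4 that rose and 2 that fell of 12 (4 and 3 adjusted over the list alone, adjusted p = 0.478). Selp and the chemokine-binding receptor Ackr1 (2.65, SE 0.45) rose, and Ccl2 (−2.81) and Cxcl1 (−1.98) fell, but neither passed in the corrected fit (−0.69, adjusted p = 0.231, and 0.10). There 4 of 11 rose and none fell (5 and 1 adjusted over the list alone), with Ackr1 at 4.35 (adjusted p = 1.07e-04 for the list, and adjusted p = 0.306 with an estimated correlation). 15 of 25 extracellular matrix genes fell and 1 rose (17 and 1 adjusted over the list alone), and 7 of 9 Dpp4-expressing progenitor genes fell (7 adjusted over the list alone). Their adjusted p-values were 0.174 and 0.0345 with an estimated correlation. With the correction 2 of 20 and 0 of 5 fell, and 3 matrix genes rose. Of 13 capillary lipid-handling genes (median 0.26, but −0.09 in the corrected fit) 2 rose and none fell, 2 also when adjusted over the list alone. None of 7 cell cycle inhibitors passed (camera adjusted p = 0.155).

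Dendritic-like cells had inflammatory and interferon genes among their rises. Rsad2, an antiviral gene, rose from 4.16 to 131 CPM (log2 fold change 5.20, SE 0.64, adjusted p = 7.21e-04), the inflammatory cytokine gene Tnf from 29.2 to 403 CPM (3.85, SE 0.35, adjusted p = 1.34e-04), and Ifit1 from 16.3 to 193 CPM (3.78, SE 0.31, adjusted p = 8.61e-05). Sult1e1 (−5.78, SE 0.29), Inmt (−5.32, SE 0.48) and Cyp26b1 (−4.96, SE 1.02) fell. 11.2% of LEAN and 4.30% of high-fat dendritic-like cells held progenitor genes, and in the corrected fit Sult1e1 and Inmt were not measured. Rsad2 (5.15, SE 0.71), Tnf (3.77, SE 0.43), Ifit1 (3.88, SE 0.33) and Cyp26b1 (−5.13, SE 0.89) passed there, as did the chemokine genes Cxcl2 (4.36, SE 0.41) and Ccl17 (−2.98, SE 0.52). 11 of 21 NF-kB target genes rose and 1 fell (11 and 1 adjusted over the list alone), and 12 rose in the corrected fit. Among them were the feedback inhibitors Tnfaip3 (2.51, SE 0.18), Nfkbia (2.10, SE 0.20) and Nfkbib (1.54, SE 0.14) (adjusted p = 3.30e-13 for the list, and adjusted p = 0.174 with an estimated correlation). Of 16 interferon-stimulated genes 6 rose and 1 fell (8 and 2 adjusted over the list alone). That list had an adjusted p = 6.31e-05 (adjusted p = 0.355 with an estimated correlation). 7 of 18 p53 target genes, a list that holds Cdkn1a, rose and none fell (8 and 1 adjusted over the list alone). Gdf15 (3.89, SE 0.36), Pmaip1 (2.03, SE 0.31) and Btg2 (1.62, SE 0.25) were among these (adjusted p = 2.66e-03, and adjusted p = 0.323 with an estimated correlation). Macrophage-mixed cells were kept here, so macrophage RNA stays open for Gdf15. Of 8910 genes tested 605 rose and 402 fell, and 632 passed in the corrected fit. Within clusters 13 and 18 the counts were 491 and 624. The 1007 calls became 581 without LEAN mouse 5 and 559 without high-fat mouse 5.

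Monocyte-like cells, the circulating precursors of macrophages, had higher Mir155hg, the host gene of an inflammatory microRNA (5.15, SE 0.91, adjusted p = 8.78e-03), Mmp12 (4.21, SE 0.61) and the chemokine gene Ccl5 (3.79, SE 0.57, adjusted p = 5.01e-03, 12 to 225 CPM). They had lower Hspa1b (−5.10, SE 0.52, adjusted p = 1.17e-03), Hspa1a (−4.98, SE 0.42) and Gdf10 (−4.79, SE 0.56). 7 of 21 NF-kB target genes rose and none fell (14 and 0 adjusted over the list alone), with Rel (1.86, SE 0.28), Nfkb1 (1.38, SE 0.21), Nfkbib (1.82, SE 0.28) and Tnfaip3 (1.99, SE 0.37) as examples. The list had an adjusted p = 4.92e-10 (adjusted p = 0.18 with an estimated correlation), and 3 members rose in the corrected fit, where Ccl5 was at 3.59 (SE 0.60) and Mir155hg, Mmp12 and Gdf10 were not measured. 123 genes rose and 159 fell of 4835, and 52 passed in the corrected fit. The 282 monocyte calls became 84, 137 and 180 without LEAN mouse 5, high-fat mouse 4 and high-fat mouse 5. NK-like cells, cytotoxic lymphocytes, had 4 of 14 NF-kB target genes up and none down (7 and 0 adjusted over the list alone). These were Nfkbiz (1.29, SE 0.19), Tnfaip3 (1.62, SE 0.24), Nfkbia (1.38, SE 0.21) and Birc3 (1.10, SE 0.24) (adjusted p = 4.22e-06 for the list, and adjusted p = 0.18 with an estimated correlation). Their largest changes were higher Cd36 (4.44, SE 0.37), Ccl8 (4.39, SE 0.58) and Mmp12 (at least 48.6-fold, no count on chow) and lower Penk (−4.62, SE 0.68), Sult1e1 (−4.59, SE 0.66) and Inmt (−3.77, SE 0.76). None of these 6 was measured in the corrected fit, and 11.1% of LEAN and 3.25% of high-fat NK-like cells held progenitor genes, and 0.337% and 4.07% macrophage genes. 82 genes rose and 40 fell of 3509 in NK-like cells, and 96 passed in the corrected fit. The 122 NK calls became 49, 39, 74 and 81 without LEAN mice 3, 4 and 5 and high-fat mouse 4.

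MHC class II genes, which present antigen, were higher in the sums of mesothelial-like cells on high-fat diet. 6 of 6 rose (6 adjusted over the list alone), with H2-Eb1 (2.40, SE 0.36), H2-DMa (2.23, SE 0.36), H2-Ab1 (2.11) and H2-Aa (1.90), and all 6 passed in the corrected fit (adjusted p = 1.28e-06 for the list, and adjusted p = 0.250 with an estimated correlation). Macrophage genes rose alongside: 11 of 12 resident macrophage genes (12 adjusted over the list alone, adjusted p = 0.0345 with an estimated correlation) and 10 of 20 lipid-associated ones, with 1 lower (12 and 4 adjusted over the list alone, adjusted p = 0.0426 with an estimated correlation). The macrophage gene Lyz2 (4.80, SE 0.15, adjusted p = 1.15e-06), the oxygenase gene Fmo2 (3.87, SE 0.50) and the proteoglycan gene Fmod (3.51, SE 0.53) rose. Inmt (−5.18, SE 0.48), Sult1e1 (−3.93, SE 0.55) and the transcription factor gene Creb5 (−3.24, SE 0.26) fell, with the same direction in the corrected fit. 10 of 24 extracellular matrix genes fell and 1 rose (11 and 2 adjusted over the list alone), with Col5a3 (−2.18, SE 0.24), Col15a1 (−1.64, SE 0.22) and Postn (−1.37, SE 0.19) down. The median of the list was −0.51, but 0.16 with the planned subtraction (adjusted p = 0.262 with an estimated correlation). 8 of 16 dissociation stress genes fell (10 adjusted over the list alone), with Hspa1b (−2.83, SE 0.43) and Hspa1a (−2.63, SE 0.39) (adjusted p = 6.22e-07 for the list, and adjusted p = 0.266 with an estimated correlation). 1901 of 12086 genes changed (1690 in the corrected fit, and 597 of 10161 within cluster 9), and 741, 803 and 586 did without LEAN mouse 4, LEAN mouse 5 and high-fat mouse 5.

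In mural-like cells the endothelial gene Cldn5 rose from 71.3 to 1704 CPM (4.52, SE 0.34), with C1qtnf9 (4.43, SE 0.51). 12 of 13 capillary lipid-handling genes rose as well (13 adjusted over the list alone), with Cd300lg (4.08, SE 0.46) and Rgcc (3.80, SE 0.36) as examples (adjusted p = 0.174 with an estimated correlation). Tnnt2 (−6.42, SE 0.97) and Hhip (−6.23, SE 1.01), the top markers of cluster 16, fell. Mmp12, with no count on chow, was at least 86.8-fold higher and Cldn11, with none on high-fat diet, at least 14.1-fold lower. 845 of 7838 genes changed by edgeR with all cells. With mixed cells left out and free RNA subtracted 0 did (754 at an unadjusted p under 0.05). Without LEAN mice 4 and 5 and high-fat mice 3 and 5 the count was 511, 528, 476 and 175.

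Over all classes 77 of 139 pairs of list and class passed the camera test, 48 up and 29 down. With an estimated correlation 6 did: the lipid-associated macrophage list in NK-like (adjusted p = 0.0345), progenitor-like, endothelial-like and mesothelial-like cells (0.0426 each), the Dpp4-expressing progenitor list in endothelial-like cells and the resident macrophage list in mesothelial-like cells (0.0345 each). The planned subtraction turned the direction of the lipid-associated macrophage list in progenitor-like (median 0.17), endothelial-like (−0.34) and mesothelial-like cells (−1.33). In the corrected fit 67 of 122 passed, and 0 with an estimated correlation.

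**Figure D4:**
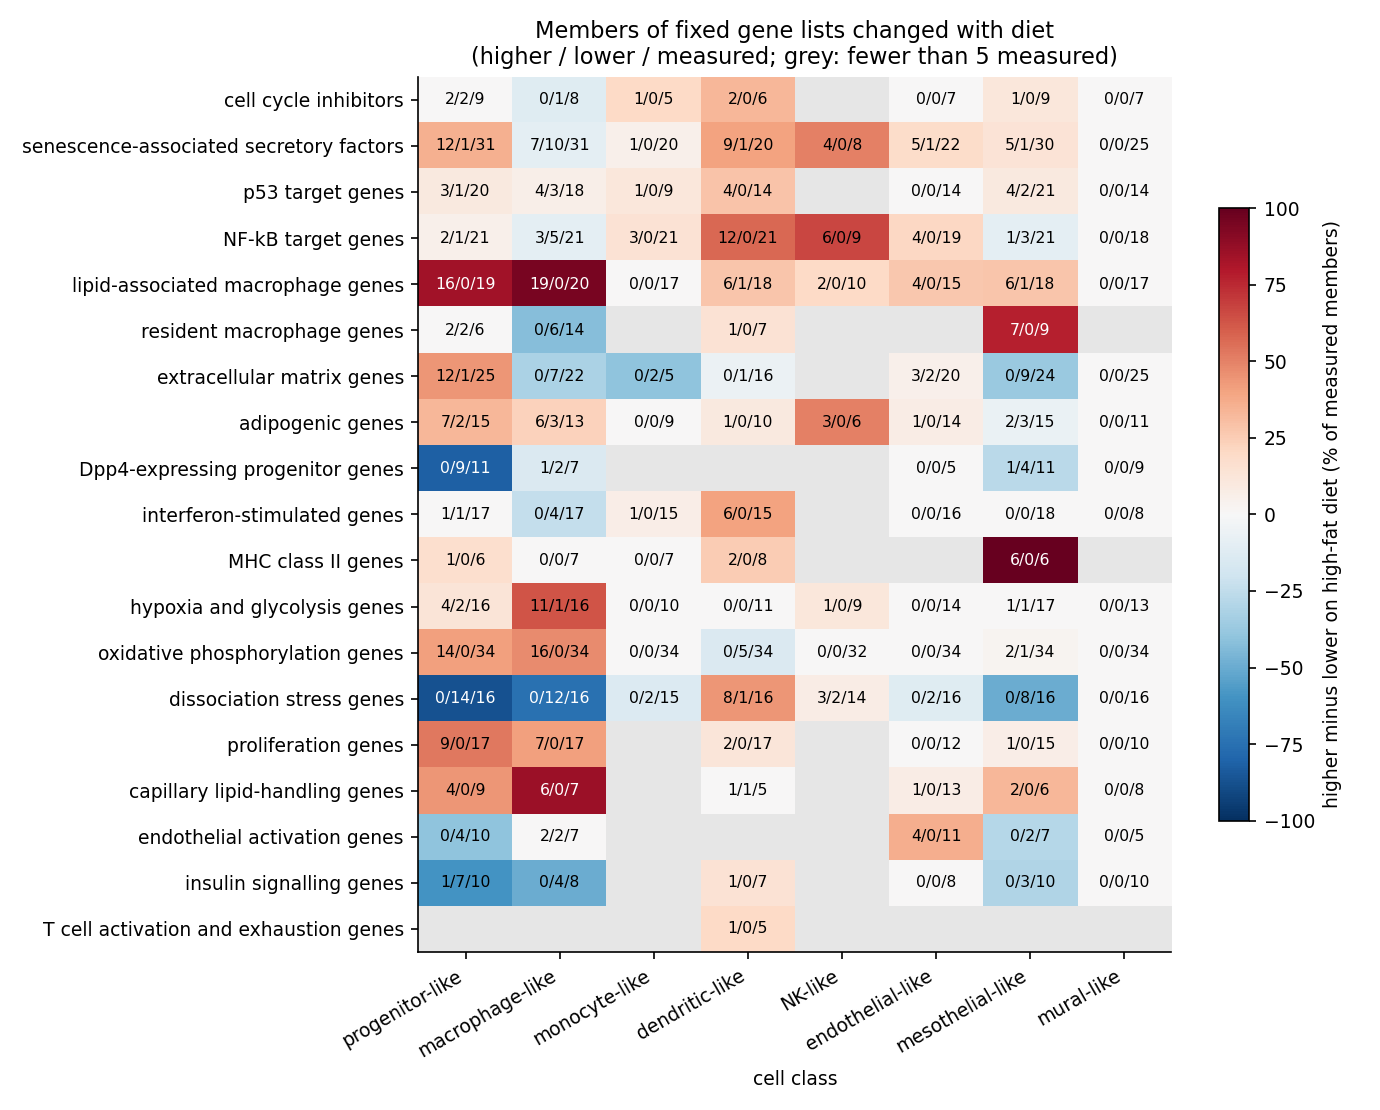
Gene lists (vertical axis) by class (horizontal axis) in the corrected fit; each cell gives the members higher, lower and measured, coloured by higher minus lower as a percentage of those measured, and grey where fewer than 5 were measured (n = 3 mice per diet). The lipid-associated macrophage list had 16 of 19 members higher in progenitor-like and 19 of 20 in macrophage-like cells, and the dissociation stress list 14 of 16 lower in progenitor-like cells.

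Whether the diet effect differed between classes was tested directly. Serpinb6b, a protease inhibitor gene, was at −0.67 in progenitor-like and 4.64 in macrophage-like cells, a difference of 5.47 (SE 0.38). The neuropeptide-processing gene Cpe was at −2.0 and 2.10 (difference 4.08, SE 0.44). Zranb3 (4.73), Fabp5 (3.82, SE 0.74) and Rnf128 (3.75) also had a more positive effect in macrophage-like cells. Cd209b (−4.91), the interferon gene Ifnb1 (−3.76, SE 0.66), Il10 (−3.67), Tmem45a (−3.52, SE 0.32) and Adamts4 (−3.45) had a more positive one in progenitor-like cells. Cd209b, Il10, Zranb3 and Rnf128 were below the count filter of progenitor-like cells alone, so their progenitor side rests on few counts. In all, 2293 of 11866 genes differed between these classes (718 more positive in macrophage-like, 1575 in progenitor-like cells). Against progenitor-like cells, endothelial-like cells had a more positive effect for Edn1 (3.58, SE 0.55), Gimap4 (3.41), Fmo2 (3.09, SE 0.36), Palmd (3.08) and Lrg1 (2.66, SE 0.37). The effect was lower for the haemoglobin genes Hba-a2 (−4.89), Hba-a1 (−4.84) and Hbb-bs (−4.80), Cxcl5 (−4.00) and Cyp4b1 (−3.99, SE 0.37), with 679 genes differing (183 and 496). Against macrophage-like cells they had a more positive effect for Fcna (8.87), Cd209f (8.81), Ccl12 (8.16), Cd209g (7.98) and Tlr7 (6.75). It was lower for Cldn5 (−7.59), Serpinb6b (−4.29), Itgax (−4.11), Fabp5 (−3.75, SE 0.38) and Akr1b8 (−3.75), with 1389 differing (895 and 494). The Cdkn1a effect did not pass in any pair, with differences of −0.30 (SE 0.22, adjusted p = 0.381), −0.24 (SE 0.31, adjusted p = 0.755) and −0.04 (SE 0.32, adjusted p = 0.962). In the corrected fit 1187 (698 and 489), 133 (89 and 44) and 371 (207 and 164) genes differed. The excess in progenitor-like cells thus turned. The planned subtraction turned Il10 (0.40), Lrg1 (−0.84) and Cldn5 (0.34). The corrected fit ended the call of Adamts4 (−0.08, adjusted p = 1.0). Gimap4 (5.34, adjusted p = 0.14), Palmd (3.52, adjusted p = 0.0540), Hba-a2 (−5.83), Hba-a1 (−5.28) and Hbb-bs (−5.72, adjusted p = 0.181 to 0.219 for the 3) no longer passed either. It also ended the calls of Fcna (adjusted p = 0.157), Ccl12 (0.186), Cd209g (0.238) and Tlr7 (0.309), at differences of 5.42 to 7.45. The 2293 became 1404 without LEAN mouse 5, and the 679 became 410, 449 and 365 without LEAN mouse 4, LEAN mouse 5 and high-fat mouse 5. The 1389 became 869, 665 and 514 without LEAN mice 3, 4 and 5, and 2978, 864 and 698 without high-fat mice 3, 4 and 5.

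Cells with and without a Cdkn1a UMI were then compared within the same mice. Macrophage-like cells with a Cdkn1a UMI had higher Il1b, the inflammasome-processed cytokine (log2 fold change 2.18, SE 0.39, adjusted p = 0.0117), and Nlrp3, the inflammasome sensor (1.48, SE 0.23). Ptgs2, which encodes the prostaglandin enzyme COX-2 (1.45, SE 0.23), Cd14 (1.29, SE 0.22) and Arl5c (1.51, SE 0.30) were higher too. Hbb-bs (−3.13), Mgp (−1.11), Hp (−1.11), Prss23 (−1.10) and Ptx3 (−1.01) were lower. 11 of 21 NF-kB target genes were higher (17 adjusted over the list alone, adjusted p = 4.77e-31, and adjusted p = 0.118 with an estimated correlation). So were 5 of 7 MHC class II genes (7 adjusted over the list alone, adjusted p = 0.0715 with an estimated correlation). 5 mice entered (2 LEAN, 3 high-fat), since LEAN mouse 3 had 5 such cells. Of 8632 genes tested 114 were higher and 22 lower, and without high-fat mouse 5 the 136 became 49. Cells of different clusters were compared here. Within cluster 7, 39 genes were higher and 112 lower, and Ptgs2 was at −0.23, while within cluster 8 31 were higher and 1 lower. With mixed cells left out Mgp was at 0.17, Prss23 did not pass (−0.34) and Hbb-bs, Hp and Ptx3 were not measured.

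Endothelial-like cells with a Cdkn1a UMI had higher immediate early and stress genes, Egr3 (1.55, SE 0.21), Csrnp1 (1.34, SE 0.15) and Apold1 (1.26, SE 0.17). The hormone gene Stc1 (1.33, SE 0.32) and the p53 target and death receptor gene Tnfrsf10b (1.28, SE 0.16) were higher as well. They had lower Timp1 (−2.29), Pgf (−1.97, SE 0.30), Il33 (−1.94), the mitotic gene Birc5 (−1.88, SE 0.41) and the tip cell gene Apln (−1.88, SE 0.38). Of these 5, Apln alone was measured with mixed cells left out (−2.84). 5 of 16 dissociation stress genes were higher (8 adjusted over the list alone, adjusted p = 4.22e-08, and adjusted p = 0.245 with an estimated correlation). 4 of 8 proliferation genes (5 adjusted over the list alone) and 7 of 25 extracellular matrix genes (22 adjusted over the list alone) were lower (adjusted p = 0.204 with an estimated correlation for each list). 123 genes were higher and 114 lower of 6886, and DESeq2 called 145. The 237 became 118, 88 and 130 without LEAN mouse 4, LEAN mouse 5 and high-fat mouse 5. In progenitor-like cells, with 4 mice of which 1 was on high-fat diet, edgeR called 0 of 8466 genes (499 at an unadjusted p under 0.05, and 11 by DESeq2). It called 1, 6 and 77 without LEAN mouse 4, LEAN mouse 5 and high-fat mouse 4. There 0 of 13 p53 target genes passed (6 higher adjusted over the list alone, adjusted p = 2.74e-11, and adjusted p = 0.118 with an estimated correlation). Nor did any of 13 proliferation genes (10 higher adjusted over the list alone, adjusted p = 3.91e-14, and adjusted p = 0.220 with an estimated correlation).

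This contrast differed between diets for some genes. In macrophage-like cells it was lower on high-fat diet for Il1b (−2.52, SE 0.28), Bcl2a1a (−2.14), Stap1 (−2.07), Bcl2a1d (−2.06) and Plek (−1.88) and higher for Cd209b (1.69). The term rests on 5 mice (3 high-fat) and was not fitted within clusters, whose shift stays open. 1 gene was higher and 35 were lower, and the 36 became 18 without high-fat mouse 3 and 62 with mixed cells left out. On thinned sums Il1b, Bcl2a1a and Plek passed, and Stap1 (−1.83), Bcl2a1d (−0.81) and Cd209b (2.06) kept their direction but did not. In endothelial-like cells it was higher for Sfrp2 (4.95), Timp1 (3.55, SE 0.41), Tnfaip6 (3.26), Gadd45b (3.11) and Basp1 (2.79). It was lower for Sema3g (−1.67, SE 0.29), Crybg1 (−1.51), Rbp7 (−1.34, SE 0.15), Cbfa2t3 (−1.16) and Npr3 (−1.10). 76 genes were higher and 28 lower. With mixed cells left out the count was 9 in place of 104. Timp1 was then at −0.42, Tnfaip6 (0.65), Gadd45b (0.14), Crybg1 (−1.22), Cbfa2t3 (−0.73) and Npr3 (−0.65) did not pass, and Sfrp2 and Basp1 were not measured. On thinned sums Rbp7 passed (−0.92), and Tnfaip6 (2.2), Sema3g (−1.13), Cbfa2t3 (−1.54) and Npr3 (−0.76) kept their direction but did not. Without LEAN mice 3 and 4 and high-fat mice 3, 4 and 5 the 104 became 266, 59, 63, 34 and 54. In progenitor-like cells the term rests on 1 high-fat mouse with 14 Cdkn1a-positive cells, so no gene is given. edgeR called 10 genes there and DESeq2 1, and the 10 became 21, 69 and 25 without LEAN mouse 3, LEAN mouse 4 and LEAN mouse 5.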

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

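The tests of free RNA in macrophage genes of progenitor-like cells and the other splits of the mice for lists, class by diet terms and the Cdkn1a term were chosen before their results were seen, and the other tests in this part only after.

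3 results stood out because the effect of diet differed between classes. These were the 2293, 679 and 1389 genes above (1187, 133 and 371 in the corrected fit). 1 data set stood out because the comparisons by mouse could not use it: 5889 LEAN and 2460 high-fat progenitor-like cells carried no hashtag. Their Cdkn1a was at 43.1 CPM on chow and 76.9 CPM on high-fat diet (49.6 and 79.7 CPM in progenitor-like cells with a hashtag), and 4.69% and 6.18% of them had a Cdkn1a UMI after thinning, with 1 library per diet and so no test. Hspa1b and Hspa1a, heat shock genes induced by tissue digestion, fell on high-fat diet in progenitor-like, macrophage-like, monocyte-like, endothelial-like and mesothelial-like cells, with Hspa1b at −3.37 to −5.10 in the first 4 of these and −2.83 in mesothelial-like cells.

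Cdkn1a rose on high-fat diet in dendritic-like, monocyte-like and mural-like cells. For dendritic-like cells the tables argue against free RNA (log2 fold change 2.14, SE 0.242, without mixed cells and after subtraction) and against a shift between clusters (2.17, SE 0.232, the lower of the values within clusters 13 and 18) as the whole source. In monocyte-like cells, stress from tissue digestion would raise the dissociation stress genes, and 4 of 16 fell and 0 rose, but free RNA stays open there, since the planned subtraction ended the call (1.04 to 0.65, SE 0.23), while the corrected fit kept it (0.95, adjusted p = 0.0470). For mural-like cells endothelial mixing stays open: without mixed cells the value was 1.57 (SE 0.499, adjusted p = 0.269) against 1.62 (SE 0.23) before. The size stayed and the error grew with fewer cells. Mixing, a shift between clusters (none fitted alone) and a change in the cells cannot be told apart. For the dendritic rise, a response to the diet is a hypothesis, while lane and diet coincide and a lane effect stays open.

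Lipid-associated macrophage genes rose on high-fat diet in progenitor-like cells. Free RNA of macrophages would need 2.03 times (median of 17 genes, interquartile range 1.54 to 5.26) the empty-droplet share that C1q genes allow (4.80%). 9 genes were above 2, most of them high on chow too, such as Lpl (12.5, 1414 CPM) and Cd63 (8.95, 1063 CPM). This argues against it as the whole source for such genes. It stays open for the list as a set and for Gpnmb (1.96), Lgals3 (1.47), Mmp12 (0.915) and Trem2 (0.830). The planned subtraction turned the direction of the list's test (median 0.17). Macrophages mixed into progenitor-like cells stay open: only 3 LEAN and 1 high-fat cells held enough C1q to be left out, and with the lipid-laden cluster 6 as their source the 17 genes needed, in the median, 1.62 times (0.831 to 4.37) the share that C1q allows, against 29.9, 8.79 and 3.51 times with clusters 7, 8 and 21. Such mixing and a change in the progenitors cannot be told apart.

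Many genes that fell on high-fat diet in endothelial-like and macrophage-like cells are genes of progenitors. In endothelial-like cells 75 of 720 genes (10.4%) still passed as lower in the corrected fit. 348 were not measured there, and the median of the others went from −0.92 to −0.62. In macrophage-like cells 39.5% of 2219 genes (877) still passed, 677 were no longer measured, and the median of the others went from −1.05 to −0.96. For the 1542 macrophage genes still measured this argues against cells called mixed as the whole source (interquartile range −1.38 to −0.62 after). Mixing under the 20% cut stays open: the planned subtraction left 856 genes lower in place of 2219. The correction selected the 1542, and a shift between clusters stays open. For the 677 (median −2.57) and in endothelial-like cells (−0.94 to −0.22 after) mixing and a fall within the cells cannot be told apart. Genes were lost or values spread widely there.

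The 6 mice can be split in 10 ways, too few for a share under 0.05. The real split (1 of the 10) called 2329 genes in progenitor-like, 4284 in macrophage-like, 282 in monocyte-like, 1007 in dendritic-like, 122 in NK-like, 1193 in endothelial-like, 1901 in mesothelial-like and 845 in mural-like cells, and the highest other split called 0 in each. For lists the numbers were 77 and 57, for class by diet 2293 and 0, 679 and 1, and 1389 and 0, and for the diet by Cdkn1a term in endothelial-like cells 104 and 9, or 9 and 9 with mixed cells left out.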

How the results depend on the processing

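The settings tried only after the results were seen were mixed cells left out, subtraction of free RNA from droplets of 100 to 500 UMIs, both together (the corrected fit), tests without cluster 21 and tests within 1 cluster; the others were planned. Values below are gene counts, log2 fold changes or differences in percentage points in the class named, and no cause was tested unless given. Depth, free RNA, mixed cells and single mice set limits. Monocyte-like, NK-like and mural-like cells had the smallest sums of the 8 classes. Of the named genes tested for diet, 4340 of 4649 values under planned settings kept their direction and side of the threshold, 161 no longer passed, 136 newly passed and 12 changed direction; under the added settings the numbers were 1503, 200, 15 and 15 of 1733. Of the lists that passed in a class, 487 of 524 planned and 191 of 226 added values stayed.

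Without a filter on low counts, which tests more genes, edgeR called 653 genes in monocyte-like, 1579 in dendritic-like, 455 in NK-like, 1901 in endothelial-like and 1408 in mural-like cells, and for cells with a Cdkn1a UMI 127 (progenitor-like), 361 (macrophage-like) and 641 (endothelial-like), with 43, 120 and 261 for its diet term. DESeq2 gave a Cdkn1a change of 0.63 in progenitor-like cells, which did not pass, 373 genes with a class by diet difference between progenitor-like and endothelial-like cells, 11 and 145 genes for cells with a Cdkn1a UMI in progenitor-like and endothelial-like cells, and 1 and 64 for the diet term there.

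The subtraction of droplets under 100 UMIs, which removes 49.5% of LEAN and 20.3% of high-fat RNA, called 1372 (progenitor-like), 1979 (macrophage-like), 67 (monocyte-like), 23 (NK-like), 203 (endothelial-like), 736 (mesothelial-like) and 334 (mural-like) genes, 44 lists, and 308, 68 and 192 class by diet differences for progenitor-like against macrophage-like, progenitor-like against endothelial-like and macrophage-like against endothelial-like cells. Cdkn1a was at 0.33 in progenitor-like and 0.65 in monocyte-like cells and did not pass. This setting turned the camera direction of lipid-associated macrophage genes in progenitor-like (median 0.17), monocyte-like (−0.20), dendritic-like (−0.31), endothelial-like (−0.34) and mesothelial-like cells (−1.33), of adipogenic genes in progenitor-like cells (0.15), of MHC class II genes in dendritic-like cells (−0.25), of extracellular matrix genes in NK-like (0.89) and mesothelial-like cells (0.16), of dissociation stress genes in NK-like (0.59) and endothelial-like cells (0.81), of capillary lipid-handling genes in endothelial-like cells (−0.29), of senescence-associated secretory factors in mesothelial-like cells (−0.11), and of Dpp4-expressing progenitor genes in mesothelial-like (0.57) and mural-like cells (0.14). It also turned Gpnmb (−9.28) and Hspa1a (1.93) in progenitor-like cells, Lgals3 (−13.61) and Irs2 (0.31) in mesothelial-like cells, Gdf15 (−0.23) and Trem2 (−0.53) in monocyte-like cells, Egr1 in NK-like cells (0.11), Pi16 in dendritic-like cells (0.98), and Akt2 (1.18), Apoe (−1.58), Egr1 (0.41) and Zfp36 (0.0019) in endothelial-like cells. The class by diet differences of Cldn5 (0.34, endothelial-like minus macrophage-like), Lrg1 (−0.84, endothelial-like minus progenitor-like) and Il10 (0.40, macrophage-like minus progenitor-like) turned as well. Values such as −13.61 arise where the subtraction leaves no counts in a group. Subtraction of droplets of 100 to 500 UMIs gave 22 genes in NK-like cells and a progenitor Cdkn1a change of 0.64, which did not pass.

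Mixed cells left out gave 2815 (macrophage-like), 96 (monocyte-like), 394 (endothelial-like) and 6 (mural-like) genes, a Cdkn1a change of 1.57 in mural-like cells, which did not pass, and a mural share lower by 1.76 points (−1.76). For the diet term of cells with a Cdkn1a UMI it gave 62 (macrophage-like) and 9 (endothelial-like) genes, with Timp1 at −0.42, and Mgp in macrophage-like cells with a Cdkn1a UMI was at 0.17. It turned the extracellular matrix genes in dendritic-like cells (median 0.14), the capillary lipid-handling genes in endothelial-like cells (−0.10), Egr1 (0.31), Gadd45b (1.80), Il6 (1.66) and Postn (1.60) in endothelial-like cells, Il6 in macrophage-like cells (0.0834) and Ly6c1 in mural-like cells (−1.75). With free RNA subtracted as well, edgeR called 2627 (macrophage-like), 52 (monocyte-like), 632 (dendritic-like), 202 (endothelial-like) and 0 (mural-like; 754 at an unadjusted p under 0.05) genes and 1187, 133 and 371 class by diet differences, and Cdkn1a did not pass in progenitor-like (0.66) and mural-like cells (1.56). This corrected fit turned the dissociation stress genes in NK-like (median 0.0910) and endothelial-like cells (0.28), the extracellular matrix (−0.0779, camera direction turned) and capillary lipid-handling genes (−0.0949) in endothelial-like cells, and Cxcl1 (0.10), Egr1 (0.43), Fbn1 (0.39), Gadd45b (2.13), Il6 (2.10) and Postn (2.34) in endothelial-like, Il6 (0.0864) in macrophage-like, and Ly6c1 (−2.46) and Plk2 (−0.33) in mural-like cells.

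Same-mouse doublets kept gave 399 genes in NK-like cells and a macrophage Cdkn1a change of 0.49, which passed. The looser cell filter gave an endothelial share difference of 5.27 points. With an estimated correlation 6 lists passed, and without cluster 21 9 macrophage lists did, the only class where that applies, as many as with it. Within clusters Cdkn1a was at 0.0907 in cluster 3 (progenitor-like), where it did not pass, and at 0.69 in cluster 7 (macrophage-like), where it did; within cluster 8 32 genes differed with a Cdkn1a UMI and Mgp was at 0.0563, and within cluster 7 Ptgs2 was at −0.23. Numbers of the hashtags did not pair the mice: over the classes the correlations of mice with the same number ran from −0.17 to 0.16. With the number as a block all the same, 666 (dendritic-like), 36 (NK-like) and 970 (mesothelial-like) genes were called, and the progenitor Cdkn1a change was 0.66, past no threshold.

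The share of cells with a Cdkn1a UMI depended on the threshold. At 2 UMIs the difference between diets was −0.433 (progenitor-like), −0.255 (macrophage-like), 8.47 (monocyte-like), 1.77 (dendritic-like), 0.960 (neutrophil-like), 1.93 (T-like), 0.629 (NK-like), 0 (B-like) and 4.97 (mural-like) points. Thinned to 2000 UMIs it was 5.16 (macrophage-like), 16.5 (dendritic-like), 18.8 (neutrophil-like) and 5.50 (B-like). Without thinning, where deeper cells show more, it was 15 (progenitor-like), 28.3 (macrophage-like), 30.6 (dendritic-like), 10.2 (T-like), 6.2 (B-like), 7.35 (endothelial-like, opposite in direction), 6.98 (mesothelial-like) and 19.7 (mural-like). For genes that differed with a Cdkn1a UMI, at least 2 of 2000 UMIs gave 265 (macrophage-like) and 585 (endothelial-like), with 126 and 30 for the diet term, and sums of thinned counts gave 89 and 59, with 1 (progenitor-like), 23 and 5 for the diet term.

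Leaving out each mouse in turn gave 1399 to 2287 genes in progenitor-like (LEAN mice 4 and 5 and high-fat mouse 4), 2705 to 5387 in macrophage-like (LEAN mouse 5), 84 to 332 in monocyte-like, 559 to 1094 in dendritic-like, 39 to 129 in NK-like, 717 to 1562 in endothelial-like, 586 to 2316 in mesothelial-like and 175 to 1119 in mural-like cells. Cdkn1a ran from 0.41 (without high-fat mouse 4) to 0.87 in progenitor-like cells, passing in 2 of 6 cases, and from 0.24 to 0.49 (without high-fat mouse 3) in macrophage-like cells. Share differences that changed sign ran from −2.14 to 0.652 (NK-like), −0.302 to 0.40 (plasma-like), −2.89 to 0.0520 (cluster 15) and −1.06 to 2.52 (cluster 20), the progenitor share with a Cdkn1a UMI from −0.243 (without high-fat mouse 4) to 3.30, and the median of extracellular matrix genes in dendritic-like cells from −1.0 to 0.0891 (without high-fat mouse 5). Class by diet counts ran from 1404 to 2895, 365 to 925 and 514 to 2978. With a Cdkn1a UMI they ran from 0 to 77 (progenitor-like), 49 to 128 (macrophage-like) and 88 to 175 (endothelial-like), and for the diet term from 21 to 69, 18 to 50 and 34 to 266.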

Other observations

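The tests in T-like, B-like and neutrophil-like cells were chosen only after the data were seen; the test of the Cdkn1a set across classes was chosen before its result was seen.

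T-like cells had at least 16 cells in each mouse. Of 7 T cell activation and exhaustion genes 5 rose on high-fat diet and none fell (6 and 0 adjusted over the list alone), and 4 rose in the corrected fit, while of 9 regulatory T cell genes 2 rose and 2 fell (3 and 3 adjusted over the list alone), and 0 and 2 did in the corrected fit. Cdkn1a rose in T-like cells (log2 fold change 1.89, SE 0.38, adjusted p = 5.58e-03; 32.4 to 95.5 CPM, n = 3 mice per diet), but high-fat mouse 3, with 1 Cdkn1a UMI in 16 cells, was at 18.4 CPM, below each LEAN mouse, and the gene was not measured in the corrected fit. In B-like cells, with at least 17 cells per mouse, 7 of 10 proliferation genes fell (10 adjusted over the list alone), and 8 did in the corrected fit. Neutrophil-like cells had Cdkn1a at 116 CPM on chow and 184 CPM on high-fat diet (0.63, SE 0.52, adjusted p = 0.552). Diet changed 610 genes in T-like, 319 in B-like and 184 in neutrophil-like cells, and 135, 218 and 36 in the corrected fit; progenitor genes were held by 12.7% of LEAN and 3.13% of high-fat T-like cells and by 11.1% and 5.08% of neutrophil-like cells, and macrophage genes by 0.373% and 5.47% of T-like, 0% and 7.48% of B-like and 0% and 6.78% of neutrophil-like cells.

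The hypothesis was that the 114 genes higher in macrophage-like cells with a Cdkn1a UMI rise with high-fat diet in dendritic-like cells, as Cdkn1a did. In the corrected fit 68 of 109 measured genes of the set rose in dendritic-like cells and 1 fell, where 6.10 rises were expected from the rate of all genes tested in both, with a median log2 fold change of 1.27 (camera adjusted p = 7.66e-63; adjusted p = 0.0573 with an estimated correlation). Monocyte-like cells had 16 up and 0 down of 105 (0.975 rises expected) and NK-like cells 20 up and 2 down of 55 (1.69 expected). Their camera adjusted p-values were 0.0573 and 0.0838 with an estimated correlation. Progenitor-like cells had 15 up and 16 down of 105 (12 rises expected), endothelial-like cells 5 up and 1 down of 84 (1.14 expected) and mesothelial-like cells 11 up and 15 down of 100 (5.70 expected). Mural-like cells had 0 up and 0 down of 84 (none expected) and a median of −0.36. Camera gave a lower direction (adjusted p = 4.39e-05, or 0.235 with an estimated correlation). The dendritic result rests on the preset correlation, and macrophage-mixed cells were kept there and in monocyte-like cells. The set holds NF-kB target genes that rose in the same cells and itself rose in NK-like cells, where Cdkn1a was low. Whether Cdkn1a takes part was not tested.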
